A study of Macaca mulatta with 23 samples.

How the data were processed

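Genomic DNA of 23 rhesus monkeys, taken from the central amygdala nucleus, was profiled by reduced representation bisulfite sequencing after MspI digestion, per the labels' protocols, with 1 library per monkey. The submitters' processing notes name Bismark 0.11.1 and the human genome build hg19. The authors deposited a single table of methylation levels as a fraction between 0 and 1, rounded to 2 decimals, for 444312 positions in each monkey. Coverage filters and the handling of strands are not given in the sources used here. The coordinates are those of the human build: 0 positions lay beyond the chromosome ends of hg19, against 7574 for hg18 and 7802 for hg38. Macaque reads placed on human coordinates are measured best where both genomes are alike, so sites that differ between the species may be missing, less certain or misread. A cytosine replaced by another base, in a single monkey or in all of them, can appear as an unmethylated site in bisulfite data.

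Fractions were multiplied by 100 and all levels are in percent. The table holds no read counts, so the depth per site is unknown, no interval or detection floor was computed, and a higher coverage minimum, set in advance as a check, was not run. Each position had a value in at least 17 monkeys, and 160349 positions (36.1%) had a value in all 23. Samples were named by hemisphere and by a number within the hemisphere. The identifiers of 12 monkeys start with r and those of 11 with B. What this difference stands for is not given in the sources used here, and it was used only as an alternative covariate and to look within each series. The sex of the monkeys was not used here.

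Positions with values in at least 20 monkeys and a range over monkeys of at least 10 percentage points were tested, 192151 in all (43.2%). Levels were fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend on the mean level), with the score and age as terms. The Benjamini-Hochberg adjustment ran over all tested positions, and a position was called at an adjusted p under 0.05, 2-sided. Hemisphere was tested with score and age in the model, and the score by hemisphere interaction with all these terms. Missing values were left out of each fit. The fits were solved for all positions at once with the limma variance step and were checked against limma itself. Files were read with the R package data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

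A region was a run of at least 3 positions with gaps of at most 200 bp. Its level in a monkey was the plain mean of the values that monkey had there, as set before the data were examined. Regions needed values in at least 20 monkeys and a range of at least 5 points, which left 21253 of 32706. Because monkeys differ in which positions are missing, a plain mean can shift with the positions present. For that reason regional means centred on the mean of each position were fitted first, in place of the plain mean. A rule that required values at 50% or more of a region's positions was then added to them, after calls for age had been seen. The plain mean was restored as the reported fit after both of these results were known, because it was the definition set in advance. Centred means, the 50% rule and both together are kept as 3 alternatives chosen after seeing the data. Their counts are given with the other alternatives.

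Counts were set beside 99 permutations of the score, the age or the hemisphere label, so that 100 assignments include the real one. Values per monkey were tested by permutation with 100000 resamples. The positions and regions named were fixed by a rule before the data were examined: the 10 positions and 10 regions with the smallest p for the score, and 5 of each for age and for hemisphere. Of these the most informative are given in full. Power was examined on simulated data with the observed mean, spread and missing values, and with normal noise drawn independently for each value. Known slopes were added to 200 units of each of 4 sizes, 800 units in 1 fit. All of these units had a mean between 20% and 80%.

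No gene annotation of hg19 was used here, so positions carry coordinates and the chromosome band of that build (from the circlize package, 0.4.16) and no gene names. For the same reason the planned tests of promoters, gene bodies, fixed gene lists, cell type markers and single genes chosen in advance were not run. A macaque gene table was at hand but belongs to another genome build, and coordinates were not converted.

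The alternatives fixed in advance were other scales of the level (logit and arcsine square root), other range filters, other variance priors, autosomes alone, other covariates, other region definitions and the omission of each monkey in turn. Alternatives added later left out the libraries that stood apart or the oldest monkey, kept only complete positions, left out positions with an SD above 20 points, used other regional means, or stayed within 1 identifier series.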

Results

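DNA methylation was measured by reduced representation bisulfite sequencing in 23 young rhesus monkeys (Macaca mulatta), in tissue of the central nucleus of the amygdala. This nucleus is a main output station of the amygdala and takes part in fear and anxiety responses. The assay cuts genomic DNA with MspI, which favours CpG-rich fragments, and bisulfite treatment then separates methylated from unmethylated cytosines. Each monkey had an anxious temperament score, a continuous measure of anxious behaviour and physiology in young primates, and an age. The samples came from the left hemisphere in 11 monkeys and from the right in 12, with 1 hemisphere per monkey. The score ran from -1.48 to 1.43 and its mean was 0.0678 ± 0.739 (SD, n = 23). Age ran from 1.1 to 2.13 years, with a mean of 1.34 ± 0.219 (SD, n = 23). The oldest monkey, left 1, was 2.13 years old and the next oldest 1.64. Left 1, right 2 and right 3, the oldest monkeys, all have identifiers starting with B. Monkeys with identifiers starting with r were 1.18 to 1.45 years old. Score and age were not detectably related (Pearson r = -0.0604; Spearman rho = -0.0536, permutation p = 0.803).

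The methylation landscape was that of CpG-rich DNA. Of the 444312 positions, 60.9% had a mean level under 20%, 18% lay between 20% and 80%, and 21.1% lay over 80%. Sites that differ between macaque and human were not identified, so some low positions may not be unmethylated cytosines. Levels were lower in regions that held more measured positions. Regions with 50 or more positions had a median level of 1.42%, those with 10 to 49 positions 15.6%, and those with 3 to 9 positions 53.2%. The mean level over the autosomes was 29.9% ± 1.57 (SD, n = 23) and that of the X chromosome 25.2% ± 1.4 (SD, n = 23). The X mean was below the autosomal mean in 23 of 23 monkeys. Among the autosomes, chromosome 19 stood highest at 37.6% ± 1.6 (SD, n = 23) and chromosome 15 lowest at 25% ± 1.33 (SD, n = 23). The 360 positions of the Y chromosome averaged 64.7% ± 1.86 (SD, n = 23). These means cover different sets of positions and were not matched for CpG density.

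Values were present at between 223368 and 440976 positions per monkey, and the read depth behind each level is unknown. Left 3 lacked a value at 49.7% of the positions and right 9 at 21.2%, against a median of 2.83% over the 23 libraries. Right 9 stood apart in a further way. At positions of intermediate level, 28.3% of its values were exactly 0 or 100%, where the other libraries ran from 0.221% to 8.65%. Its correlation with the mean of the other monkeys was 0.905 across positions, which are not independent replicates, and those of the other libraries were 0.971 or more.

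The first question was whether the overall level of methylation followed anxious temperament. It did not detectably do so. The mean level per monkey was 29.7% ± 1.56 (SD, n = 23), and its correlation with the score was r = -0.0871 (permutation p = 0.692, adjusted p = 0.83) with rho = -0.0361 (permutation p = 0.871, adjusted p = 0.939). Without the monkeys at the ends of the score, right 4 and left 11, r was -0.216. The slope adjusted for age was -0.147 ± 0.452 percentage points per score unit (SE, n = 23). The share of positions under 20% gave r = 0.0373 (permutation p = 0.866) and the share over 80% r = -0.167 (permutation p = 0.445). These tests were 2-sided and belonged to a family of 6 relations with score and age, adjusted by the Benjamini-Hochberg method. Within the 12 monkeys with identifiers starting with r, the mean level gave r = -0.0893, and within the 11 starting with B it gave r = -0.274. Libraries with more missing values had a lower mean level (r = -0.785, permutation p = 1e-04; rho = -0.634, permutation p = 0.00153). That relation was -0.89 within the r series and 0.015 within the B series, so it did not hold in both. The mean of each monkey covers its own set of positions. Over the positions it had, left 3 averaged 25.5% and right 9 27%. At positions with a value in every monkey they averaged 19.4% and 20.4%, against a median of 19.8% over the libraries.

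**Figure D1:**
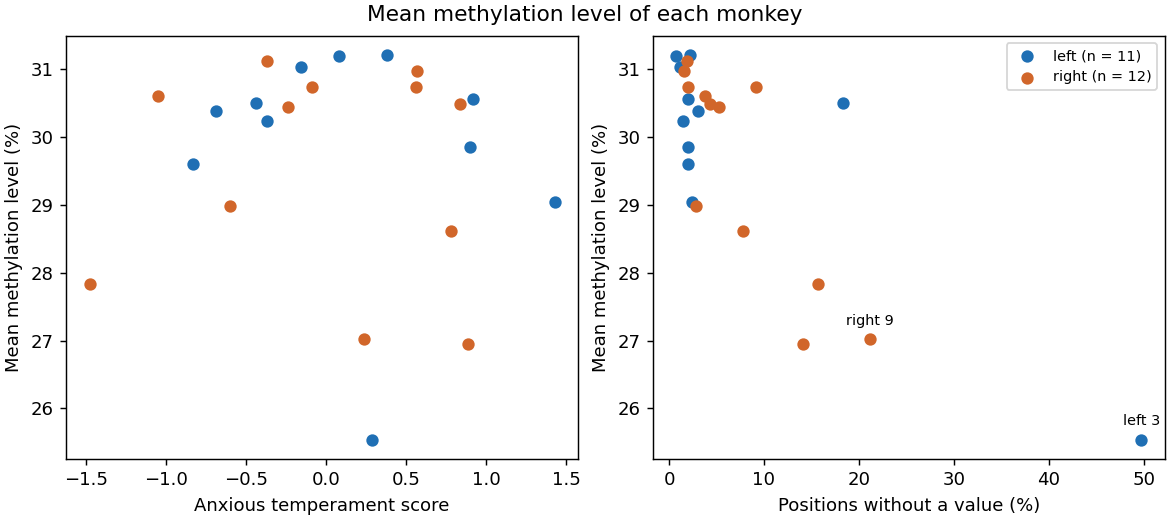
Mean methylation level of each of the 23 monkeys, in percent, against the anxious temperament score on the left and against the percentage of positions without a value on the right. Each point is 1 monkey, coloured by hemisphere. No trend with the score is seen (r = -0.0871), while left 3, which lacked 49.7% of the positions, had the lowest mean level, 25.5%. Each mean covers the positions that monkey had. At positions with a value in every monkey left 3 had a mean of 19.4%, against a median of 19.8% over the libraries.

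The central comparison of the study asked which sites vary with anxious temperament, with age as the covariate. No position passed the limma test at an adjusted p of 0.05 among the 192151 tested, and the smallest adjusted p was 0.334. At an unadjusted p under 0.05 there were 5991 positions, or 3.12%, and under 0.01 there were 976, of which 479 had levels that went up with the score and 497 levels that went down. Permuted scores gave as many or more in 71 of 100 assignments, the real one included, with a median of 1268 over the others.

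The position with the smallest p lies on chromosome 9 at 131343400 of the human build hg19, in band 9q34.11. Its slope was -22.87 ± 3.53 percentage points per score unit (SE, n = 20), with p = 1.74e-06 and the adjusted p of 0.334 given above. The level was 0 in 10 monkeys, whose scores were 0.24 or higher, and 15% or more in the other 10, whose scores were 0.08 or lower. This position passed the threshold on the logit scale (limma adjusted p = 0.00678), on the arcsine scale (0.0142) and without right 11 (0.0477). In band 14q22.1, the level at chromosome 14, 53108135 had a slope of 12.3 ± 2.36 points per score unit (SE, n = 20). At chromosome 4, 138945579 (4q28.3) the slope was -39.47 ± 7.86 (SE, n = 20) and the levels spanned 0 to 100%. At chromosome 12, 33354802 (12p11.1) it was -35.1 ± 7.32 (SE, n = 21), with rho = -0.493. Levels there were 3% or less, or between 61% and 92%, with none between. All low levels were in monkeys with scores of 0.38 or higher. Among monkeys with such scores, right 1, right 6 and right 8 stood at 88%, 72% and 91%. The other 6 of the 10 leading positions had slopes between -4.539 and 18.45 points per score unit. For these 9 positions the limma adjusted p was 1. At the 9 of the 10 positions that had a measured neighbour within 50 bp, the median slope of the neighbours ranged from -0.538 to 0.266 of the slope at the position.

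**Figure D2:**
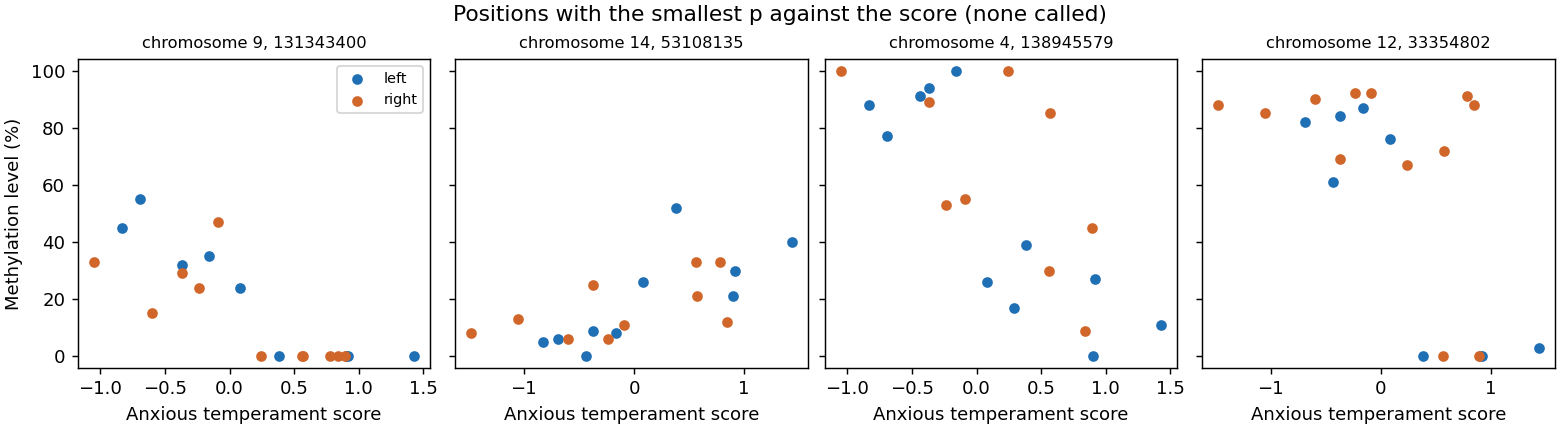
Methylation level in percent against the anxious temperament score at the 4 positions with the smallest p, each point 1 monkey coloured by hemisphere. At chromosome 9, 131343400, the 10 monkeys with scores of 0.24 or higher sit at 0 and the 10 with scores of 0.08 or lower at 15% or more. None of the 4 positions passed the adjusted threshold with all monkeys on the percent scale.

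Averaging neighbouring positions did not yield associations either. Of 21253 regions tested with limma, 0 passed at an adjusted p of 0.05, 680 had an unadjusted p under 0.05, and 100 had an unadjusted p under 0.01, of which 46 went up with the score and 54 down. Permuted scores gave as many in 72 of 100 assignments. The leading region, on chromosome 12 from 56219453 to 56219489 (12q13.2), held 4 positions and averaged 90.35% ± 6.93 (SD, n = 22). Its slope was -5.414 ± 1.22 points per score unit (SE, n = 22; limma adjusted p = 1). A region of 6 positions on chromosome 11 from 134257669 to 134257766 (11q25) had a slope of 7.591 ± 1.78 (SE, n = 22). The region of the 10 with the most positions, 24 on chromosome 19 from 19371786 to 19371901 (19p13.11), averaged 46.5% ± 4.69 (SD, n = 23). Its slope was 4.343 ± 1.13 points per score unit (SE, n = 23). The others had slopes between -8.604 and 15.46, each with a limma adjusted p of 1. In simulated data with the observed means, spreads and missing values, slopes were added only to units with a mean between 20% and 80%. A slope of 20 points per score unit was called at 59% of 200 changed positions and a slope of 10 at 8.5%. For regions, slopes of 10 and 5 were called at 78% and 39%. Each simulation held 800 changed units of 4 sizes in 1 fit, which eases the adjusted threshold, and fewer changed units were not simulated. The simulated noise was normal and independent between units. Of the unchanged simulated positions 0.985% had an unadjusted p under 0.01, against 0.508% of the observed positions. The shares called thus do not describe the tested positions in general, nor those with means outside 20% to 80%. Without right 9 and left 3, the counts at an unadjusted p under 0.01 were 1523 positions and 171 regions, and without right 2 there were 169 regions. Scores were not permuted for these counts.

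**Figure D3:**
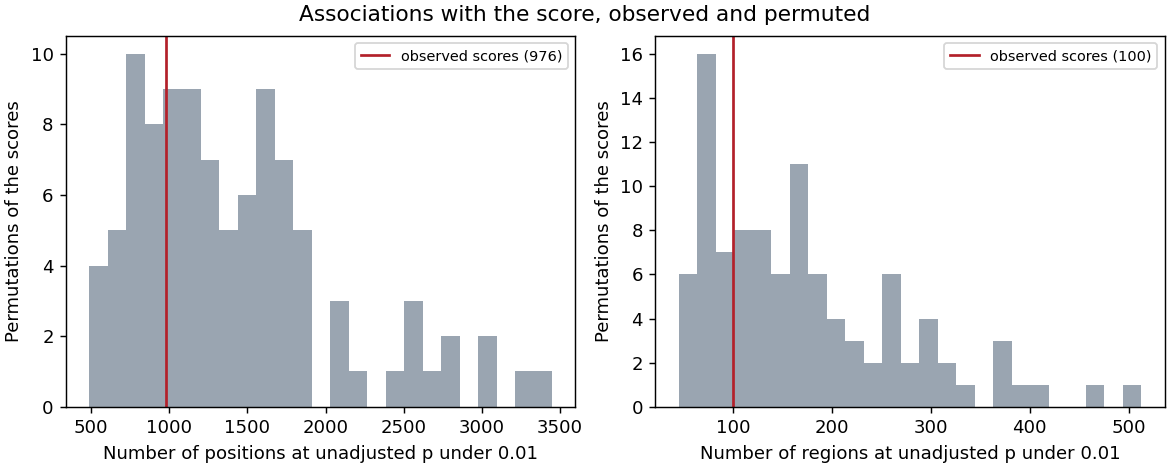
Number of positions (left) and regions (right) with an unadjusted p under 0.01 for the anxious temperament score. Grey bars count the 99 permutations of the scores and the red line marks the observed scores, at 976 positions and 100 regions, inside the permuted range of 488 to 3452 positions and 45 to 513 regions.

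The hemisphere labels allow a comparison of right with left samples, adjusted for score and age. No position passed the limma test (smallest adjusted p 0.93). At an unadjusted p under 0.05 there were 6678 positions, and under 0.01 there were 972, 553 higher in right samples and 419 lower. The position with the smallest p, on chromosome 19 at 7709633 (19p13.2), averaged 92.67% ± 3.12 (SD, n = 9) in left and 99% ± 1.41 (SD, n = 11) in right samples, a difference of 6.78 ± 1.14 points (SE; limma adjusted p = 0.93). No region passed either (smallest adjusted p 0.975; 663 at an unadjusted p under 0.05). The leading region was a run of 22 positions on chromosome 1 from 205312527 to 205312672 (1q32.1). It averaged 17.95% ± 2.58 (SD, n = 11) in left and 23.85% ± 3.32 (SD, n = 12) in right samples, with an adjusted difference of 5.705 ± 1.27 points (SE; limma adjusted p = 0.975). The mean level over all positions was 29.93% ± 1.6 (SD, n = 11) in left and 29.54% ± 1.58 (SD, n = 12) in right samples (permutation p = 0.577, adjusted p = 0.638 over 5 measures). At positions with a value in every monkey, left samples averaged 19.67% ± 0.52 (SD, n = 11) and right samples 19.84% ± 0.497 (SD, n = 12; permutation p = 0.425, adjusted p = 0.638).

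The slope on the score was also compared between hemispheres. No position and no region had an interaction that passed the limma test (smallest adjusted p 1 and 0.232). At an unadjusted p under 0.05 there were 6224 positions and 756 regions. For the mean level, the slope in right samples differed from that in left samples by 0.588 points per score unit (permutation p = 0.598).

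Age was the covariate of the design, and its own term called 102 positions, 64 with levels that went up with age and 38 down (limma, adjusted p under 0.05). They depended on the scale of the level: with all monkeys kept, 0 positions were called on the logit scale and 3 on the arcsine scale. The 5 positions with the smallest p on the percent scale had limma adjusted p from 0.062 to 0.421 on the logit scale. On the percent scale the calls ended without left 1, the oldest monkey, when 0 positions passed. At 100 of the 102, left 1 alone had the highest or the lowest level of all monkeys. The count was 183 without right 2 and 164 without right 3. It was 42 without the variance trend, 24 with the identifier series as a covariate, 24 with the mean level and 17 at complete positions. Permuted ages called as many positions in 49 of 100 assignments. At chromosome 14, 89913338 (14q32.11), the slope was 34.29 ± 4.16 points per year (SE, n = 20; limma adjusted p = 0.00514), and left 1 stood at 35% against a mean of 5.4% over all monkeys. Without left 1 that slope was 26.4 (limma adjusted p = 1). At chromosome 10, 74917051 (10q22.2), it was -81.64 ± 10.1 (SE, n = 20; limma adjusted p = 0.00514), with left 1 at 0 and a mean of 86.75%, and -30.9 without left 1. At chromosome 11, 68925646 (11q13.3), left 1 was again at 0 where the mean was 91.68%, and the slope was -79.66 ± 10.6 (SE, n = 22; limma adjusted p = 0.00648), and -6.67 without left 1.

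Among regions, 12 were called for age with limma, 7 up and 5 down, and 0 without left 1. Permuted ages called as many regions in 43 of 100 assignments. The count was 14 on the logit scale, 7 on the arcsine scale, 21 without right 2, between 3 and 6 without any single one of 14 other monkeys, and 3 with the identifier series as a covariate. In 8 of the 12, left 1 had values at fewer than 50% of the region's positions. With regional means kept only for monkeys with values at 50% or more of the positions, 1 region was called. The region of 32 positions on chromosome 6 from 39281861 to 39281986 (6p21.2) averaged 8.424% ± 6.52 (SD, n = 23) and stood at 37.44% in left 1. Its slope was 24.25 ± 3.64 points per year (SE, n = 23; limma adjusted p = 0.00684), and 3.73 without left 1 (limma adjusted p = 1). The mean level per monkey gave r = 0.296 with age (permutation p = 0.159, adjusted p = 0.438; rho = 0.366, permutation p = 0.0858). The share of positions over 80% gave r = 0.415 (permutation p = 0.0483, adjusted p = 0.29; rho = 0.447, permutation p = 0.0341, adjusted p = 0.205) and r = 0.33 without left 1 and right 2. Within the r and B series that r was -0.0155 and 0.605. Left 1 is in the B series, and ages in the r series ran only from 1.18 to 1.45 years. The r series could therefore show little of age.

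**Figure D4:**
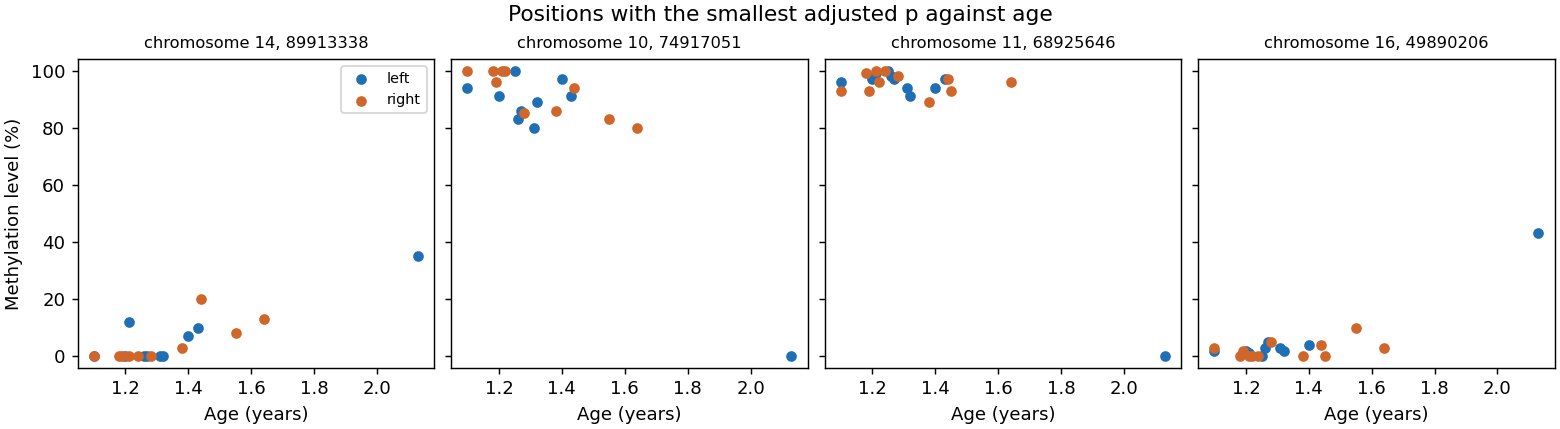
Methylation level in percent against age in years at the 4 positions with the smallest p for age, each point 1 monkey coloured by hemisphere. The point at 2.13 years is left 1, which stands at 35% or more, or at 0, away from the other monkeys.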

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

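The alternatives that leave out several monkeys, keep complete positions, stay within 1 identifier series or change the regional mean were chosen after seeing the data. Depth is unknown, so its effect could not be examined, and alternatives based on coverage or genes were not run. No paired analysis was possible because each monkey gave 1 hemisphere and the numbers within hemispheres do not pair samples. Where a value moved, the cause was not tested unless fewer positions or monkeys entered the fit, apart from an age region described below.

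For anxious temperament, 1 position was called on the logit scale and 1 on the arcsine scale, and 0 to 1 with single monkeys left out (1 without left 11 and 1 without right 11). The count at an unadjusted p under 0.01 was 619 positions with a range of at least 20 points, 1523 without right 9 and left 3, and 200 at complete positions, and ran from 757 to 1383 with single monkeys left out. For regions it was 171 without right 9 and left 3 and 34 for complete regions, and ran from 82 to 169. The wider range filter and the complete sets tested fewer units. Scores were not permuted for these counts, so they do not rank the strength of association. The correlation of mean level and score changed sign at complete positions (r = 0.0286545, permutation p = 0.895) and ran from -0.241839 to 0.00729956 with single monkeys left out, the upper end without right 12. No hemisphere or interaction call appeared under the alternatives run.

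The age calls moved most. Age and identifier series were entangled: left 1, right 2 and right 3, the oldest monkeys, are in the B series. Ages in the r series ran only from 1.18 to 1.45 years, so counts and slopes within it say little about age. Called positions numbered 0 on the logit scale, 3 on the arcsine scale, 42 without the variance trend, 24 with the identifier series as a covariate, 24 with the mean level as a covariate, 17 at complete positions, 0 without right 9, left 3 and left 1, and 0 in the r and 0 in the B series alone. With single monkeys left out they ran from 0 (left 1) to 183 (right 2). Called regions numbered 7 on the arcsine scale, 6 with hemisphere as a covariate, 3 with the identifier series, 4 with the mean level, 4 without right 9 and left 3, 0 when left 1 was also left out, 6 for complete regions, and 0 in the r and 0 in the B series alone. With single monkeys left out they ran from 0 (left 1) to 21 (right 2), with 3 to 6 without any single one of left 2, 6, 7, 8, 9, 10 and 11 or right 1, 4, 5, 6, 8, 9 and 12. Regional means centred on each position gave 14 called regions, means from monkeys with values at 50% or more of the positions gave 1, and both together gave 1.

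Some age regions changed sign. The slope of the region from chromosome 16, 67140747 was -50.81 points per year as reported. It was 1.20136 without right 9, left 3 and left 1, 1.66148 with centred means, 1.54172 with centred means at 50% or more of the positions, and 4.35069 in the r series. The 50% rule alone gave -0.224643, the same as the fit without left 1. Centred means kept left 1, so the reported slope of this region depended on which of its positions left 1 had. In the r series the region from chromosome 3, 23984816 had 21.6462 and that from chromosome 6, 39281861 had -3.55931. No named position changed sign in the alternatives in which it was fitted.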

Other observations

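Permutations of the score and of the hemisphere labels were planned in advance, as was the fit without the oldest monkey. The bounds used to read these were set after their results were seen. The tests of chance for the age counts and of the oldest monkey's library were chosen after those results were seen. So were those of the monkey given the oldest age in permutations, and of the libraries that stand apart as a source of the leading score positions. The tests of chance for the interaction counts and for the call on the logit scale, and those of sequence variants and of right 9, were set before theirs.

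A few multi-position regions differed widely between monkeys. Of 13670 regions with 10 or more positions and values in 20 or more monkeys, 685 had an SD over 10 points, where the median SD was 2.08. The most variable, chosen after its values were seen, was a run of 12 positions on chromosome 11 from 2021948 to 2022065 in band 11p15.5, a band that in humans holds a cluster of imprinted genes. It averaged 31.3% ± 28 (SD, n = 22), with monkeys from 1.08% to 72.7%. The next, 14 positions on chromosome 12 from 120150382 to 120150488 (12q24.23), averaged 48% ± 26.2 (SD, n = 21) and ran from 0.214% to 83.8%. Of 6009 regions with 20 or more positions, 348 had a mean between 40% and 60%, and 0 of these combined an SD under 4 points with intermediate levels at 80% of their positions. Among 97687 isolated pairs of positions 1 bp apart, as both strands of a CpG would be, the median difference in mean level was 1.21 points, yet 11% differed by over 20 points and 3538 had one position under 20% and the other over 80%.

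Chance could not be excluded for most counts. For the score, 71 of 100 assignments gave as many positions at an unadjusted p under 0.01 as the real 976 (highest other 3452), and 72 as many regions as the real 100 (highest other 513). For hemisphere, 60 of 100 splits gave as many positions as the real 972 (highest other 2927) and 61 as many regions as the real 100 (highest other 442). For the interaction, 73 of 100 gave as many positions as 1094 (highest other 3930) and 63 as many regions as 144 (highest other 526). That region count ran from 79 without left 11 to 209 without left 6, and without right 9 and left 3 the interaction counts were 1780 positions and 234 regions. For age, 49 of 100 assignments called as many as 102 positions (highest other 30810) and 43 as many as 12 regions (highest other 2085). The largest counts went with 1 library: in the 4 assignments that gave the oldest age to right 9, between 29115 and 30810 positions were called, and in the other assignments 3581 or fewer. In the 3 permuted assignments that left the oldest age with left 1, between 42 and 115 were called. On the logit scale, where chromosome 9, 131343400 was called for the score, 2 of 100 assignments, the real one included, called 1 position or more (highest other 1). That scale was 1 of many alternatives, and the real scores called 0 positions on the scale set as the main one, so this position remains a hypothesis.

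The calls for age may rest on left 1. None of the called positions passed without it (0). Over the other monkeys 87.25% kept the sign of the slope, but those monkeys were part of what selected the positions, so this share decides nothing. In the 3 permuted assignments that left the oldest age with left 1, the other ages were shuffled and 42 to 115 positions were called. Left 1 at the oldest age thus gave counts of this size without the real ages of the others. Whether left 1 alone carries each called position stays open. Few reads across its library were argued against by 0.308% of its values at exactly 0 or 100%, below the median of 0.604%. That share was taken over intermediate positions with a value in every monkey, so it does not give the reads of left 1 at the called positions. In 8 of the 12 called regions left 1 had values at fewer than 50% of the positions. Sequence variants carried by left 1 also stay open: its median departure at neighbours within 50 bp was 0.148 of that at the called positions (6 against 40.5 points), under the bound set in advance for this cause. That bound was found wrong after the result, since left 1 alone was the highest or lowest at 100 of the 102 called positions, which were thus selected for its departure while the neighbours were not, and other causes could give a low value too. Age itself stays open, since 1 monkey cannot separate age from the individual.

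Right 9 stood apart from the other libraries. Few DNA molecules behind each value could account for this: over 10 classes of level its mean stayed within 2.73 points of the others, while its departures at single positions had an SD of 29.7 points against 8.34 to 18 elsewhere. The class means do not set right 9 apart, since every other library stayed within 4.495 points too. Depth is unknown, so few molecules cannot be told apart from few reads. Another tissue or a wrong label was to show as departures shared by both strands, and these correlated by 0.152, under the 0.3 set as evidence against it. That bound was found wrong after the result, since noise lowers a correlation, and the covariance, which noise does not lower, was 135.1 against 108.1 or less in the others. Another tissue or a wrong label therefore stays open, and no biological explanation was tested.

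The list for the score was led by 10 positions whose neighbours within 50 bp, where there were any, had slopes of other sizes or signs. The slopes at these positions were nearly unchanged without right 9 and left 3. At 3 of the positions neither had a value, and over the other 7 the slope without both had a median of 1 times that with them and ran from 0.987 to 1.03 times. Their scores lie within 0.301 SD of the mean score, which leaves them little weight on a slope whatever their values. The test could therefore hardly have come out otherwise, and no verdict on these libraries is drawn from it. Whether other positions would lead without both was not tested. Whether sequence variants at the position contribute cannot be told apart from chance: the median neighbour slope was -0.0497 of that at the position over 9 positions, but the shares went both ways, from -0.538 at chromosome 14, 53108135 to 0.266 at chromosome 3, 62106863. Chromosome 9, 131343400 had no neighbour to examine, and an effect of temperament was tested at each position and passed the adjusted threshold at 0 of them with all monkeys on the percent scale.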
